A study of Mus musculus with 9 samples.

How the data were processed

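The study measured RNA of LSK cells sorted by flow cytometry from the bone marrow of mice in 3 groups of 3 libraries, Sed, Ex and ExSed. Per the labels' protocols, marrow was first depleted with antibodies against T, NK, B, erythroid and myeloid surface markers, among them CD3, CD19, B220, CD49b, TER119, CD11b and Gr1. The remaining cells were stained for c-Kit, Sca-1, CD48 and CD150 and sorted. RNA was isolated with a kit for small cell numbers and sequenced on an Illumina NextSeq. Age at harvest was 16 to 17 weeks in the labels of every group.

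The values used are estimated counts per gene, which the authors deposited as whole numbers for 35288 Ensembl gene IDs. Per the submitters' processing notes, Salmon 0.11.3 and the genome build GRCm38.p6 were used. The annotation release, the summary from transcripts to genes, the rounding and the strand setting are not given in the sources used here. Salmon's estimates are not whole, so they were rounded before deposit, and rounding again changed nothing. Salmon divides reads shared by near-identical transcripts, so the values of ribosomal protein genes with processed pseudogenes, of globin genes and of immunoglobulin segments are uncertain. Of the IDs, 35028 had a symbol in the gene name table, and 10094 had 0 counts in all 9 libraries. Where 2 IDs shared a symbol the one with fewer counts kept its ID as its name, which was so for 32 IDs. Coordinates, transcript lengths and GC content came from the GENCODE annotation of GRCm38.

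Totals ran from 22772276 counts in ExSed 1 to 63171802 in ExSed 3. Intervals of ratios are exact binomial intervals at 95% on the counts summed over a group. A group with 0 counts was given a floor of 3 counts over the group. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Every pair of libraries differed by more than sampling noise: the lowest chi-square per gene between a pair was 59.35.

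Genes were kept with edgeR's filterByExpr (minimum count 10), which left 16403 genes holding at least 99.83% of the counts of each library. Counts were scaled with TMM factors, and edgeR 4.0.16 quasi-likelihood F-tests were fitted to all 9 libraries with 1 coefficient per group (R 4.3.3). The comparisons were Ex against Sed, ExSed against Sed, ExSed against Ex, and any difference among the 3 groups. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Members of a list were also adjusted over that list alone, without correction across the 35 lists, so some can pass there by chance. SE of a log2 fold change is the estimate divided by the square root of its F. CPM are TMM-scaled, and log2 CPM used a prior count of 2. The 35 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. List medians were the same with genes of 0 counts in a group, and over 3 in the other, set at their bound. The lists cover lineage priming, the cell cycle, stress and signalling, metabolism, translation and the other cell types that a marrow sort could hold.

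Named genes followed a rule. For each comparison it took the 10 genes with the highest and the 10 with the lowest fold change among those past the threshold, with a mean of at least 1 CPM over the 9 libraries and values that did not overlap between groups. With fewer than 5 in a direction, it took the 5 of smallest p meeting the other conditions. It added 14 fixed genes and up to 4 members of smallest p from each list described. Predicted genes and pseudogenes were left out of names. The tests, lists, rule and the alternatives from DESeq2 to the left-out libraries, given next, were fixed before the data were examined. Immunoglobulin, megakaryocyte and mast cell genes given per library outside this rule were chosen after their values were seen.

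Alternatives were DESeq2 1.42.0, limma-voom, DESeq2's size factors or total counts in edgeR, no filter, a mean of at least 50 counts, robust estimation, an FDR of 0.1, only the 6 libraries compared, the replicate number as a block, and each library left out in turn. After the data were seen, a smooth trend of each library on transcript length and GC content (splines with 4 degrees of freedom) was removed as an offset, and 3 libraries rich in short transcripts were left out together. Length was known for 16306 of the tested genes. The length slope of a library was fitted over 6583 genes with a mean log2 CPM above 5. Correlations over the 9 libraries used all 362880 permutations, two-sided.

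The fits were checked on counts simulated for Ex against Sed with the means, library sizes and spread of the real libraries, of which 16011 genes were tested. This check was written after the real data had first been fitted. Of 50 genes per size, edgeR recovered 0 changed 2-fold, 7 changed 4-fold, 26 changed 8-fold and 35 changed 16-fold, and called 1 unchanged gene. A list, that of oxidative phosphorylation, shifted by 0.5 on the log2 scale was called by camera. Each gene was drawn on its own, so simulated members shared no variation. In the real libraries their estimated correlation was 0.48, so this does not show how camera performs on lists whose members move together. Figures were drawn with matplotlib 3.10.9.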

Results

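RNA was sequenced from LSK cells, the lineage-negative, Sca-1-positive, c-Kit-positive fraction of mouse bone marrow that holds haematopoietic stem cells and early multipotent progenitors. The cells came from the long bones and pelvis of male C57BL/6 mice that entered the experiment at 7 to 8 weeks of age. Mice of the Ex group had a running wheel for 6 weeks. Mice of the ExSed group had a wheel for 6 weeks and then lived without it for 3 weeks. Mice of the Sed group were housed with an igloo in place of a wheel. The labels give an age of 16 to 17 weeks for every group, which a start at 7 to 8 weeks and 6 weeks with a wheel do not reach. They do not say whether Ex mice started later or were kept longer, so Ex and ExSed may differ in more than the withdrawal. Each group had 3 libraries, with 37215312, 41361210 and 31383010 counts in Sed 1, Sed 2 and Sed 3, 55406699, 36959870 and 30445060 in Ex 1, Ex 2 and Ex 3, and 22772276, 31038242 and 63171802 in ExSed 1, ExSed 2 and ExSed 3. The labels do not state whether the libraries of a group came from separate animals or from pools, so p-values measure the spread between these libraries, which may be partly technical. The samples allowed 3 questions: what differed after 6 weeks of wheel access, what differed from Sed after the wheel had been withdrawn, and what differed between the groups with and without withdrawal.

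The sorted population carried the transcripts of its gate in every library. Kit, the stem cell factor receptor of the c-Kit gate (chromosome 5, 75574916 to 75656722, GRCm38), stood at 667 ± 418 CPM in Sed, 642 ± 521 CPM in Ex and 1101 ± 306 CPM in ExSed (SD, n = 3). Ly6a, which encodes Sca-1, stood at 179 ± 8.04, 183 ± 90.5 and 166 ± 17.4 CPM in the same order. Hlf and Mecom, transcription factors of stem cells, had 273 ± 55.5 and 60.5 ± 35.9 CPM in Sed. Libraries of the same group were no more alike than libraries of different groups: the median correlation of log2 CPM across genes was 0.904 within groups and 0.903 between them. The biological coefficient of variation was 63.7%.

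The libraries also differed by transcript length. Short transcripts were relatively abundant in Sed 3, Ex 2 and Ex 3, and relatively scarce in Ex 1 and ExSed 3. Among 186 genes with transcripts under 500 nucleotides, the median deviation from the mean of the 9 libraries was 0.43 in Sed 3, 0.25 in Ex 2 and 0.54 in Ex 3 on the log2 scale, against -0.56 in Ex 1 and -0.305 in ExSed 3. The slope of this deviation per doubling of length ran from -0.171 in Ex 3 to 0.198 in Ex 1. It was 0.0322, 0.0617 and 0.137 in ExSed 1, ExSed 2 and ExSed 3, and -0.0331, 0.0576 and -0.169 in Sed 1, Sed 2 and Sed 3. Kit was lowest in the libraries rich in short transcripts, with 332, 385 and 299 CPM in Sed 3, Ex 2 and Ex 3 and 534 to 1301 CPM in the 6 others.

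**Figure D1:**
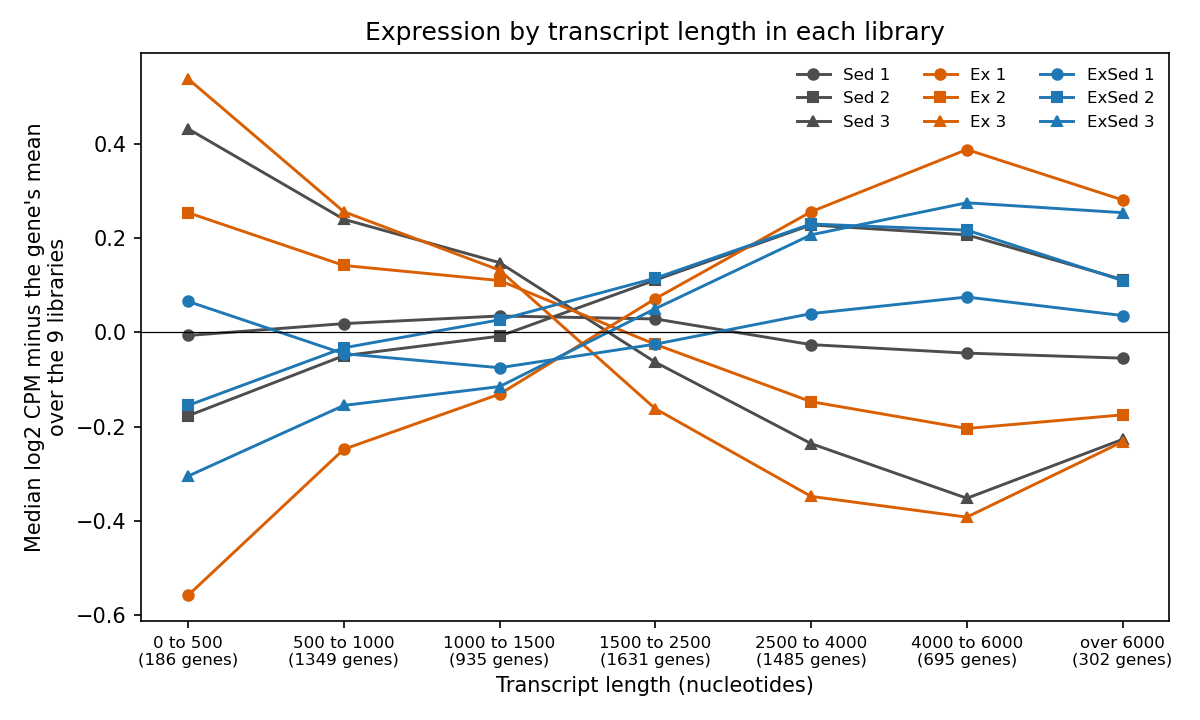
Median deviation of log2 CPM from each gene's mean over the 9 libraries (y axis) in bins of transcript length in nucleotides (x axis, number of genes in parentheses); one line per library, coloured by group, with a symbol for the replicate number. In the shortest bin the medians ran from -0.56 in Ex 1 to 0.54 in Ex 3, both libraries of the Ex group.

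Wheel access was compared with sedentary housing first. No gene passed the threshold, and the genes with the smallest p-values included several that were nearly absent from all 3 Ex libraries. Fas, the death receptor of the TNF receptor family (ENSMUSG00000024778, chromosome 19, 34290666 to 34327772), had 0 counts in the 3 Ex libraries and 192 in the 3 Sed libraries, 1.84 ± 1.19 CPM (SD, n = 3), at least 71.2-fold lower in Ex against a floor of 3 counts over the group. Tgm5, a transglutaminase (ENSMUSG00000053675, chromosome 2, 121046111 to 121085841), had 1 count in Ex and 350 in Sed, a ratio of 389 with a 95% counting interval of 69.4 to 15400. Lpar4, a lysophosphatidic acid receptor, had 1 count in Ex and 245 in Sed, a ratio of 272 (48.4 to 10800). Endou, an endoribonuclease, had 2 and 294 counts, a ratio of 163 (44.9 to 1360). Insrr, the insulin receptor-related receptor (chromosome 3, 87796951 to 87816101), had 0.137 ± 0.139 CPM in Ex and 5.59 ± 1.72 CPM in Sed. In the other direction, Gopc, a Golgi PDZ-domain protein (chromosome 10, 52335850 to 52382124), had 38.65 ± 12 CPM in Ex and 8.59 ± 3.8 CPM in Sed, and Lsm11, a component of the U7 ribonucleoprotein, 16.7 ± 4.54 and 4.55 ± 1.45 CPM. Plcl1, Zfp174 and Slc6a20a were low genes with 2.97 ± 1.29, 4.88 ± 2.66 and 3.85 ± 1.71 CPM in Ex against 0.0763 ± 0.0816, 0.669 ± 0.255 and 0.27 ± 0.259 CPM in Sed. The edgeR quasi-likelihood test gave Tgm5 the smallest adjusted p of the comparison, 0.645, and Gopc a log2 fold change of 2.17 (SE 0.524) with an adjusted p of 1. All 10 of these genes had values that did not overlap between the 3 Ex and the 3 Sed libraries, a condition of being named. Gopc, Plcl1, Zfp174, Slc6a20a, Tgm5 and Insrr overlap another counted gene on the annotation, and the strand setting of the counting is not given in the sources used here.

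Over 16403 genes tested, edgeR called 0 genes between Ex and Sed at an adjusted p under 0.05. At an unadjusted p under 0.05 it gave 429 genes, 197 higher and 232 lower in Ex, where 820 would be given by chance. Limma-voom also called 0, with 439 genes at an unadjusted p under 0.05. DESeq2 called 48, with 833 at an unadjusted p under 0.05. Of those 48, 16 were higher in Ex, 27 had a count of 0 in at least 1 of the 6 libraries, and the median level was 1.7 CPM. They included Fas, Tgm5, Lpar4, Insrr, Endou, Plcl1, Zfp174, Gopc, Lsm11 and Slc6a20a. Of the 48, edgeR tested 45, and 42 of those had an unadjusted edgeR p under 0.05. The 3 Ex and 3 Sed values did not overlap for 871 genes, 5.31% of those tested, where chance gives 10%.

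None of the 14 stem cell, lineage and cell cycle genes chosen beforehand passed between Ex and Sed, over all genes tested or adjusted over the list alone. Mki67, the proliferation marker, had a log2 fold change of -0.07 (SE 0.263), with 291 ± 47 CPM in Ex and 305 ± 86.3 CPM in Sed (n = 3; edgeR adjusted p = 1). The cyclin-dependent kinase inhibitors Cdkn1a, Cdkn1b and Cdkn1c had log2 fold changes of 0.13 (SE 0.352), -0.27 (SE 0.256) and 0.96 (SE 1.26). Flt3 had -0.08 (SE 0.462), Slamf1 0.37 (SE 0.548), Cd48 0.11 (SE 0.24), Cxcr4 -0.02 (SE 0.422), Mpo -0.10 (SE 0.387), Hlf 0.14 (SE 0.214) and Mecom 0.54 (SE 0.497). Lepr, the leptin receptor, was near the detection limit, at 0.63 ± 0.395 CPM in Ex and 1.38 ± 1.4 CPM in Sed, a log2 fold change of -1.134 (SE 0.94). With standard errors of this size, larger changes than those measured are not excluded.

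Among 35 gene lists, 4 stood apart between Ex and Sed in the camera test with its preset correlation, and none did with an estimated correlation. Mast cell and basophil genes lay higher in Ex: 8 of 9 members were higher, with a median log2 fold change of 1.01 (camera adjusted p = 0.000784; adjusted p = 0.947 with an estimated correlation). Prss34, a basophil serine protease (chromosome 17, 25298394 to 25300165), had 149, 166 and 503 CPM in Ex 1, Ex 2 and Ex 3 and 37.7, 85.1 and 16.9 CPM in Sed 1, Sed 2 and Sed 3. It was the only member of its list to pass adjusted over the list alone (0.0493), which does not correct across the 35 lists. Mcpt8, another basophil protease, had 102 ± 102 CPM in Ex and 25.6 ± 3.39 CPM in Sed. Immediate-early genes, which respond rapidly to stimulation or cell handling, were higher in Ex for 18 of 22 members, with a median of 0.58 (camera adjusted p = 0.0105; 0.947 as the adjusted p with an estimated correlation). Klf6 had 74.9 ± 4.69 CPM in Ex and 43.4 ± 9.61 CPM in Sed, Btg2 94.6 ± 5.85 and 66.1 ± 5.15 CPM, and Fos 31.4 ± 25.5 and 5.17 ± 5.89 CPM. Dendritic cell genes were higher for 11 of 13 members, with a median of 0.50 (camera adjusted p = 0.0148; 0.947 as the adjusted p with an estimated correlation). Clec9a had 4.61 ± 0.567 CPM in Ex and 1.26 ± 1.33 CPM in Sed, and H2-Aa 201 ± 53.1 and 150 ± 15.8 CPM. Platelet and megakaryocyte genes were lower in Ex for 9 of 10 members, with a median of -1.32 (camera adjusted p = 0.00371; 0.947 as the adjusted p with an estimated correlation). Ppbp, a platelet chemokine, had 80.3 CPM in Sed 3 and at most 6.28 CPM in Sed 1, Sed 2 and the Ex libraries. Tubb1, the platelet tubulin, had 0 counts in Ex and 105 in Sed, at least 38.9-fold lower in Ex.

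Each of these 4 list calls depended on single libraries. The camera adjusted p of the mast cell and basophil list was 0.351 without Sed 1, 0.068 without Sed 2, 0.0562 without Ex 2 and 0.286 without Ex 3. Its median over the same 9 members was then 0.666 (SD 0.881), 1.12 (SD 1.59), 0.981 (SD 1.21) and 0.488 (SD 0.72), against 1.01 (SD 1.04) with all libraries. In each of these fits 2 further members passed the filter, and without Ex 3 the median over all 11 was 0.0951. The camera adjusted p of the platelet and megakaryocyte list was 0.585 without Sed 3 and 0.134 without Ex 1. For immediate-early genes it was 0.192 without Sed 2, 0.0515 without Sed 3 and 0.288 without Ex 1, and for dendritic cell genes 0.385 without Sed 1 and 0.618 without Ex 2. Without Sed 3, Ex 2 and Ex 3 together, a choice made after the data were seen that left Ex 1 alone in its group and took the spread from the other groups, it was 0.752 for the mast cell, 0.324 for the platelet and 0.754 for the dendritic cell list. The immediate-early list had 0.00392 there, which decides nothing: its level was 1.38 in Ex 1, the library kept, and -0.199 and 0.202 in Ex 2 and Ex 3 on the log2 scale. Among genes with a mean of at least 50 counts it was 0.189 for the platelet list. The count of lists was 7 without Ex 3. Of the members in these lists, 0 mast cell, 2 platelet, 7 immediate-early and 1 dendritic cell gene also stood in another list.

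The other 31 lists were not called between Ex and Sed, with camera adjusted p from 0.136 to 0.996. S phase genes had a median log2 fold change of -0.04 and G2/M genes -0.07. The long-term HSC list had a median of 0.08, the myeloid-primed list 0.04, the lymphoid-primed list -0.02 and the erythroid and megakaryocyte-primed list -0.10. The LSK sort markers stood at -0.01, the quiescence list at 0.20 and the niche adhesion list at -0.14. Nuclear-encoded oxidative phosphorylation had a median of 0.03, mitochondrially encoded mRNA 0.0062, glycolysis -0.08, fatty acid oxidation -0.04, hypoxia 0.04 and antioxidant response 0.0027. Cytosolic ribosomal proteins stood at 0.09, MYC targets at -0.0027, heat shock and unfolded protein response at -0.07, the p53 targets at 0.04, interferon response at -0.08, TNF and NF-kB signalling at 0.06, the leptin, insulin, glucocorticoid and adrenergic list at 0.03 and the circadian clock at 0.15. Of the lists for other cell types, red cells stood at 0.21, B cells at -0.75, T and NK cells at 0.95, type 2 innate lymphoid cells at -0.13, neutrophils at 0.35, monocytes and macrophages at 0.10, stromal cells at -0.12 and endothelial cells at 0.07. The median, mean and camera direction differed in sign for the oxidative phosphorylation, red cell, leptin and insulin, antioxidant, long-term HSC, p53, mitochondrial, LSK marker and monocyte lists. Fas was the only p53 target to pass adjusted over the list alone (0.00648). Fry's mixed test, which asks whether genes change in either direction, called the T and NK cell list (adjusted p = 0.00117), whose members with the smallest p-values were Cd5, with 0.0703 CPM in Ex and 2.44 CPM in Sed, and Klrd1, with 2.6 and 0.667 CPM.

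**Figure D2:**
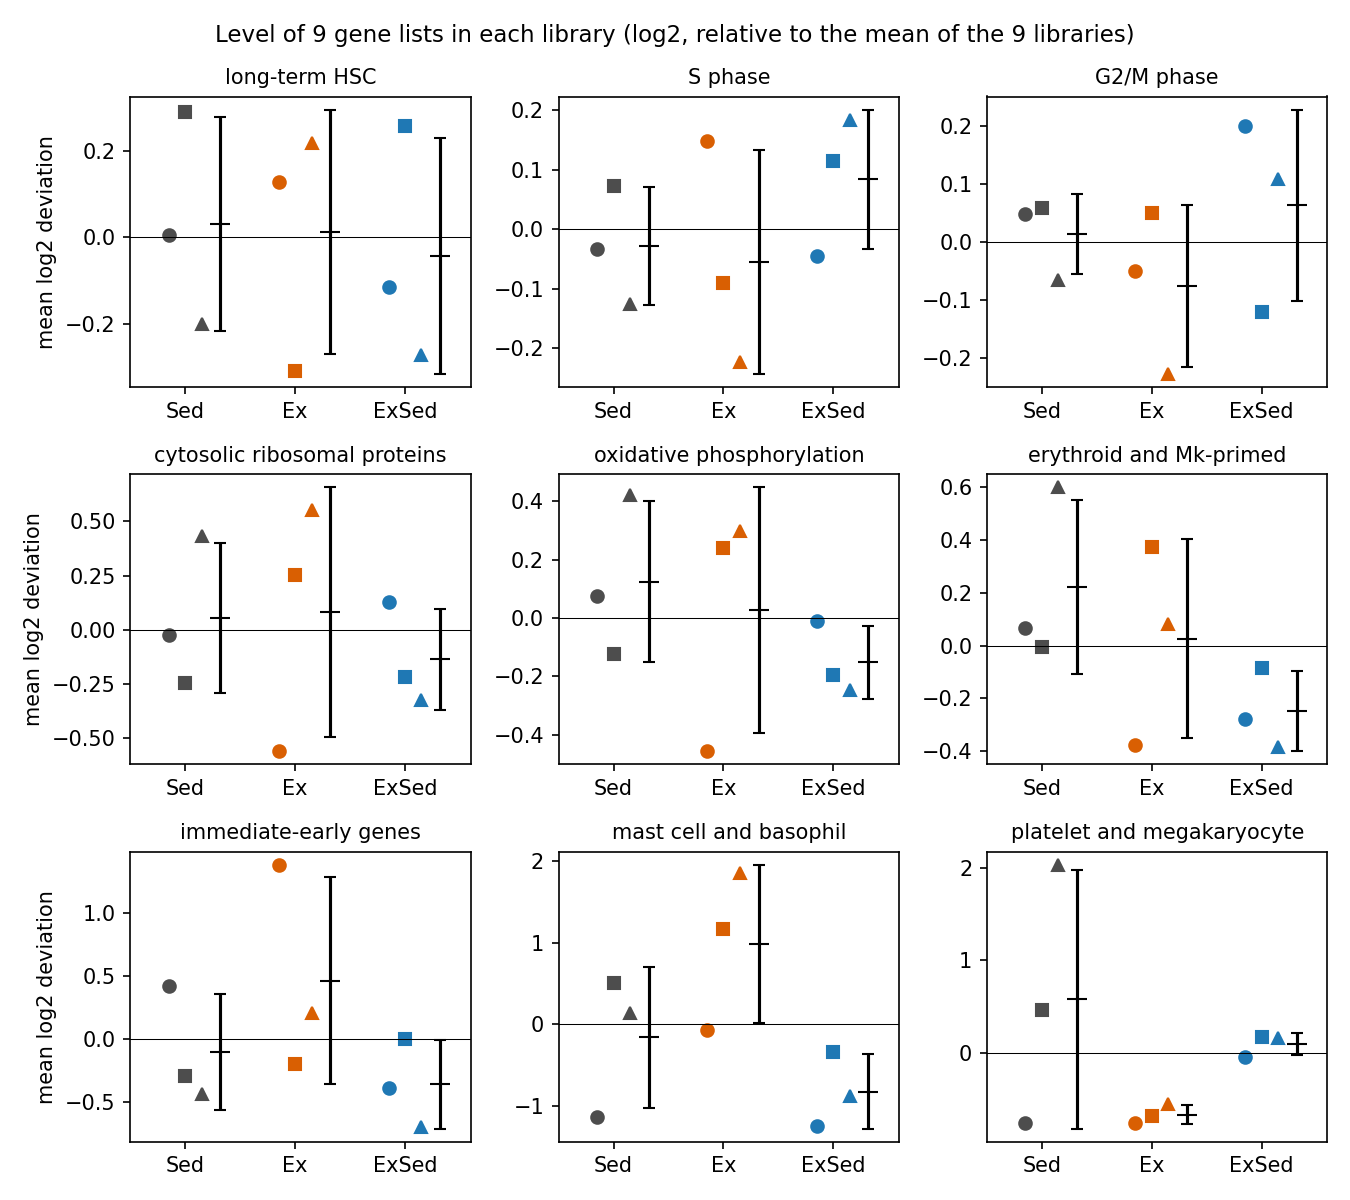
Level of 9 gene lists in each library: mean over members of log2 CPM minus the gene's mean over the 9 libraries (y axis) for Sed, Ex and ExSed (x axis), with one symbol per library by replicate number (circle 1, square 2, triangle 3) and the mean ± SD of each group as a black bar (n = 3). The Ex libraries ran from -0.46 to 0.30 for oxidative phosphorylation, a range that held the values of the 3 ExSed libraries and of Sed 1 and Sed 2.

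The second comparison set the group with the wheel withdrawn against Sed. No gene passed the threshold here either. Sh3tc2, an endosomal recycling protein (chromosome 18, 61953075 to 62024402), had 1 count in the 3 ExSed libraries and 410 in the 3 Sed libraries, a ratio of 432 with a 95% counting interval of 77.2 to 17100. Gpr84, a receptor for medium-chain fatty acids, had 0.368 ± 0.197 CPM in ExSed and 4.99 ± 0.652 CPM in Sed (SD, n = 3), and the cadherin Celsr2 0.342 ± 0.0424 and 3.44 ± 1.59 CPM. Slc38a5, an amino acid transporter (chromosome X, 8271133 to 8280179), had 5.9 ± 2.38 CPM in ExSed and 28.9 ± 8.57 CPM in Sed, and the carboxylesterase Ces2g 25.4 ± 3.16 and 66.2 ± 7.25 CPM. In the other direction, Etv5, an ETS transcription factor (chromosome 16, 22381309 to 22439719), had 53.4 ± 10.5 CPM in ExSed and 24 ± 6.37 CPM in Sed. Rab36 had 14.1 ± 4.43 and 3.07 ± 1.94 CPM, Fut4 12.7 ± 4.22 and 3.23 ± 2.42 CPM, Zfp174 3.6 ± 1.44 and 0.669 ± 0.255 CPM, and Plcl1 1.33 ± 0.712 and 0.0763 ± 0.0816 CPM. The log2 fold changes by edgeR were -1.38 (SE 0.32) for Ces2g, -2.29 (SE 0.513) for Slc38a5 and 1.155 (SE 0.342) for Etv5, each with an adjusted p of 0.999. None of these 10 genes passed. Values that did not overlap between the 2 groups were a condition of being named.

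Over the 16403 genes, edgeR called 0 genes between ExSed and Sed, with 307 at an unadjusted p under 0.05 (136 higher and 171 lower in ExSed) where chance gives 820. Limma-voom called 0, with 388 at an unadjusted p under 0.05. DESeq2 called 30, with 699 at an unadjusted p under 0.05. Of these 30, 8 were higher in ExSed, 16 had a count of 0 in at least 1 library, and the median level was 1.84 CPM. Sh3tc2, Gpr84, Celsr2, Slc38a5, Ces2g, Plcl1 and Zfp174 were among them. Of the 30, edgeR tested 27, and 25 of those had an unadjusted edgeR p under 0.05. The values of 1513 genes, 9.22%, did not overlap between the groups, where chance gives 10%. Of the 14 genes chosen beforehand none passed, over all genes or adjusted over the list alone. Kit had a log2 fold change of 0.72 (SE 0.589), Flt3 0.37 (SE 0.463), Mki67 -0.43 (SE 0.263), Cdkn1a -0.09 (SE 0.352), Cdkn1b -0.35 (SE 0.256), Cdkn1c -1.50 (SE 1.29), Ly6a -0.10 (SE 0.322), Slamf1 -0.54 (SE 0.549), Cd48 0.01 (SE 0.24), Cxcr4 0.43 (SE 0.423), Lepr -1.21 (SE 0.942), Mpo -0.04 (SE 0.387), Hlf -0.12 (SE 0.214) and Mecom 0.54 (SE 0.497).

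In camera with the preset correlation 6 lists stood apart between ExSed and Sed, and 0 did with an estimated correlation. Nuclear-encoded genes of oxidative phosphorylation, the mitochondrial respiratory chain and ATP synthase, were lower in ExSed for 44 of 49 members, with a median log2 fold change of -0.37 (camera adjusted p = 2.5e-07; adjusted p = 0.733 with an estimated correlation). Ndufb10 had 94.7 ± 13.6 CPM in ExSed and 148 ± 46.2 CPM in Sed, and Cox5b 160 ± 18.1 and 226 ± 66.4 CPM. Cytosolic ribosomal protein genes were lower for 72 of 77 members, with a median of -0.21 (camera adjusted p = 5.13e-05; 0.851 as the adjusted p with an estimated correlation), and Rps13 had 226 ± 25.7 and 292 ± 79.7 CPM. Genes of erythroid and megakaryocyte-primed progenitors were lower for 14 of 18 members, with a median of -0.49 (camera adjusted p = 5.13e-05; 0.687 as the adjusted p with an estimated correlation). Rhd, a red cell surface antigen, had 7.94 ± 2.12 CPM in ExSed and 36.4 ± 28.3 CPM in Sed. Car1, a carbonic anhydrase, had 198 ± 6.92 and 644 ± 405 CPM, and Gata1, the erythroid transcription factor, 27.6 ± 5.35 and 52.7 ± 18.4 CPM. Red cell genes were lower for 11 of 12 members, with a median of -0.60 (camera adjusted p = 1.24e-05; 0.687 as the adjusted p with an estimated correlation), among them Rhag with 6.52 ± 3.74 and 29.5 ± 15.9 CPM. The antioxidant list was lower for 19 of 22 members, with a median of -0.24 (camera adjusted p = 0.0485; 0.687 as the adjusted p with an estimated correlation), while its member of smallest p, Srxn1, was at 23 ± 8.59 CPM in ExSed and 9.98 ± 7.58 CPM in Sed. Neutrophil genes were higher for 9 of 14 members, with a median of 0.21 (camera adjusted p = 0.0159; 0.733 as the adjusted p with an estimated correlation). Ly6g had 0.923 ± 0.817 and 0.0195 ± 0.0171 CPM, and Mmp9 8.69 ± 4.49 and 1.13 ± 1.96 CPM.

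The levels of 11 of the 35 lists went with the length slope of the libraries at an adjusted exact permutation p under 0.05 (Pearson, two-sided). The slope was fitted over genes that can include list members, so for lists of short transcripts such a correlation is partly built in. Over the 9 libraries, the level of the oxidative phosphorylation list had a Pearson correlation of -0.985 with the length slope (Spearman -0.983; exact permutation p = 5.51e-06 and 4.96e-05, adjusted over 35 lists 0.000193 and 0.00174), and -0.983 without Ex 3 and Sed 3, the libraries farthest from the median slope. The ribosomal list had -0.961 (Spearman -0.967; exact permutation p = 7.44e-05 and 0.000165, adjusted 0.0013 and 0.00192), and -0.92 without these libraries. The red cell list had -0.876 (Spearman -0.883; exact permutation p = 0.00224 and 0.00308, adjusted 0.0112 and 0.0154), and -0.759 without them. The erythroid and megakaryocyte-primed list had -0.863 (Spearman -0.883; exact permutation p = 0.00289 and 0.00308, adjusted 0.0126 and 0.0154), and -0.903 without them. The antioxidant list had -0.9 (Spearman -0.933; exact permutation p = 0.00105 and 0.00075, adjusted 0.00735 and 0.00656), and -0.873 without them. With the length and GC trend of each library removed, an analysis added after the data were seen, the oxidative phosphorylation list stayed at -0.27 (camera adjusted p = 0.000165). The erythroid list at -0.42 (0.000263), the red cell list at -0.71 (0.000165) and the neutrophil list at 0.24 (0.00278) were still called. Without Sed 3 the medians moved from -0.368 to -0.15 (SD 0.112 over members) for oxidative phosphorylation, from -0.491 to -0.246 (SD 0.54) for the erythroid and from -0.603 to -0.279 (SD 0.709) for the red cell list, so a large part of each rested on that library. They were still called there, at camera adjusted p of 0.0124, 0.0124 and 0.00979. With the trend removed, the call of the ribosomal list ended with a smaller median, -0.133 (SD 0.127 over members) against -0.207 (SD 0.118) before (camera adjusted p = 0.0799). That of the antioxidant list, close to the threshold before, ended at 0.0693 with a median that was no smaller, -0.276 (SD 0.445) against -0.24 (SD 0.468). The call of the ribosomal list also ended without Sed 3 (camera adjusted p = 0.872) and without ExSed 3 (0.098). That of the antioxidant list ended without Sed 3 (0.289, with a median of -0.131 and an SD of 0.294), ExSed 3 (0.317) or Ex 2 (0.0707), and that of the neutrophil list without Sed 1 (0.53), Sed 2 (0.251) or ExSed 2 (0.0629). Neutrophil levels were -2.62, -1.3 and 1.08 in Sed 1, Sed 2 and Sed 3 on the log2 scale and 0.528, 1.41 and 0.753 in the ExSed libraries. The small median thus rested on Sed 3: the camera adjusted p was 9.94e-25 without it, and without Sed 3, Ex 2 and Ex 3 the median was 2.01 (1.99e-16). Without Sed 3, Ex 2 and Ex 3 together the ribosomal list had 0.726 and the antioxidant list 0.175, and among genes with a mean of at least 50 counts the antioxidant list had 0.0581. The count of lists was 10 without ExSed 2.

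The other 29 lists were not called between ExSed and Sed, with camera adjusted p from 0.089 to 0.933. Their medians included 0.07 for S phase, 0.02 for G2/M, -0.12 for long-term HSC, -0.23 for myeloid-primed, -0.03 for lymphoid-primed, 0.12 for interferon response and 0.22 for niche adhesion genes. The mast cell and basophil list had a median of -0.575. The median, mean and camera direction differed in sign for the p53, dendritic cell, T and NK cell, G2/M and leptin and insulin lists. In this comparison 3 genes passed adjusted over the list alone and missed the threshold over all genes. Igkc, the immunoglobulin kappa constant region (chromosome 6, 70726435 to 70726966), had 403, 45.6 and 444 CPM in Sed 1, Sed 2 and Sed 3 and 1.51, 0.365 and 0.542 CPM in ExSed 1, ExSed 2 and ExSed 3 (0.0238 over the B cell list). Jchain, the joining chain of secreted immunoglobulin, had 82.7 ± 59.8 CPM in Sed and 0.783 ± 0.64 CPM in ExSed (0.0367 over the lymphoid-primed list). Col1a1, a stromal collagen, had 0.123 ± 0.0606 and 0.922 ± 0.476 CPM (0.0455 over the stromal list).

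**Figure D3:**
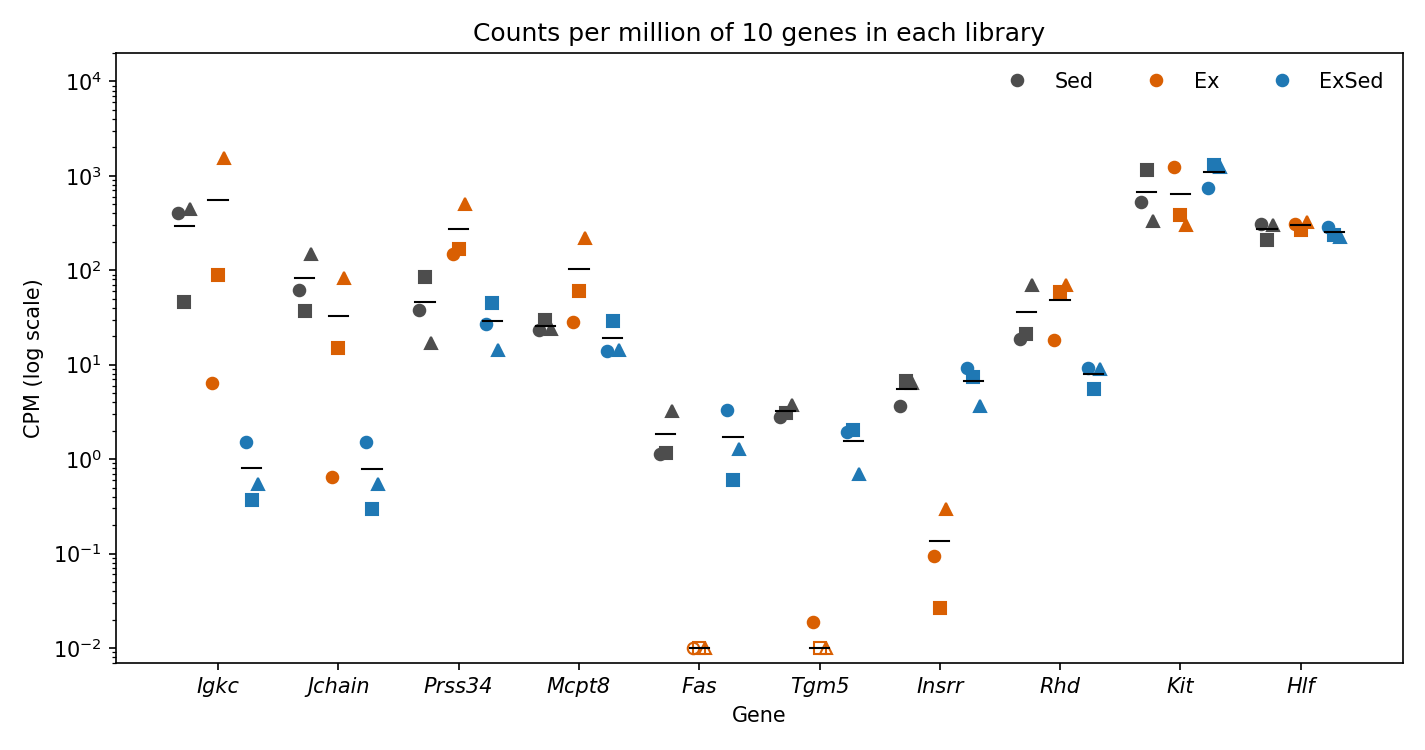
CPM (y axis, log scale) of 10 genes (x axis) in each library, coloured by group, with one symbol per library by replicate number and a black line at the mean of each group. Open symbols on the lowest line mark values under 0.01 CPM: Fas had 0 counts in all 3 Ex libraries, and Igkc stood at 1.51 CPM or less in the 3 ExSed libraries.

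The third comparison, ExSed against Ex, asked what differed between mice 3 weeks after the wheel was withdrawn and mice with a wheel. The genes nearly absent from Ex were present in ExSed: Fas had 175 counts in ExSed and 0 in Ex, at least 61.5-fold higher, and Tgm5 151 and 1, a ratio of 159 with a 95% counting interval of 28.2 to 6330. Lpar4 had a ratio of 274 (48.8 to 10900) and Endou of 170 (46.8 to 1410), and Insrr had 6.715 ± 2.82 CPM in ExSed against 0.137 ± 0.139 CPM in Ex (SD, n = 3). Lower in ExSed were Sh3tc2, with 1 count against 616 in Ex (ratio 584, 104 to 23100), Slc38a5, with 5.9 ± 2.38 against 33.9 ± 17 CPM, and Gpr84, with 0.368 ± 0.197 against 4.33 ± 3.04 CPM. Prss34 had 28.9 ± 15.5 CPM in ExSed and 273 ± 199 CPM in Ex. Igkc had 0.805 ± 0.615 and 551 ± 874 CPM, with 6.44 CPM in Ex 1 and 1560 CPM in Ex 3. All 10 missed the threshold by edgeR, with adjusted p from 0.782 to 0.92.

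Between ExSed and Ex edgeR called 0 of 16403 genes, with 619 at an unadjusted p under 0.05 (287 higher and 332 lower in ExSed). Limma-voom called 0, with 648 at an unadjusted p under 0.05. DESeq2 called 85, with 1170 at an unadjusted p under 0.05. Of the 85, 50 were higher in ExSed and 41 had a count of 0 in at least 1 library, and all 10 genes above were among them. EdgeR tested 82 of the 85, and 81 of those had an unadjusted edgeR p under 0.05. The values of 1405 genes, 8.57%, did not overlap, where chance gives 10%. Of the 14 genes chosen beforehand none passed. The log2 fold changes were 0.78 (SE 0.589) for Kit, 0.45 (SE 0.463) for Flt3, -0.36 (SE 0.263) for Mki67, -0.91 (SE 0.552) for Slamf1, -2.46 (SE 1.33) for Cdkn1c and within 0.45 of 0 for the other 9. For any difference among the 3 groups edgeR called 0 genes, with 350 at an unadjusted p under 0.05, limma-voom 0 with 432, and DESeq2 53 with 915.

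In camera with the preset correlation 7 lists stood apart, all lower in ExSed than in Ex, and 0 did with an estimated correlation. The mast cell and basophil list was lower for 9 of 9 members, with a median log2 fold change of -1.08 (camera adjusted p = 2.98e-06; adjusted p = 0.397 with an estimated correlation). Prss34 (0.0135) and Mcpt8 (0.0263) passed adjusted over the list alone. The immediate-early list was lower for 17 of 22 members, with a median of -0.82 (camera adjusted p = 0.000109; 0.417 as the adjusted p with an estimated correlation). Btg2 had 58.8 ± 4.76 CPM in ExSed and 94.6 ± 5.85 CPM in Ex, and Zfp36 45.5 ± 6.73 and 88.1 ± 29.8 CPM. The quiescence list, which shares members such as Btg2 and Klf4 with the immediate-early list, was lower for 20 of 28 members, with a median of -0.40 (camera adjusted p = 0.00368; 0.595 as the adjusted p with an estimated correlation). Gfi1, a transcriptional repressor, had 4.13 ± 0.601 and 12.3 ± 6.4 CPM. Ribosomal protein genes were lower for 74 of 77 members, with a median of -0.29 (camera adjusted p = 7.88e-06; 0.84 as the adjusted p with an estimated correlation). Oxidative phosphorylation was lower for 40 of 49 members, with a median of -0.38 (camera adjusted p = 0.000182; 0.84 as the adjusted p with an estimated correlation). Red cell genes were lower for 10 of 12 members, with a median of -0.74 (camera adjusted p = 0.000854; 0.688 as the adjusted p with an estimated correlation). The erythroid and megakaryocyte-primed list was lower for 11 of 18 members, with a median of -0.27 (camera adjusted p = 0.0346; 0.84 as the adjusted p with an estimated correlation). Its member Rhd had 7.94 ± 2.12 CPM in ExSed and 49 ± 27.2 CPM in Ex (0.0498 adjusted over the list alone), whereas Itga2b had 105 ± 48.9 and 51 ± 26.6 CPM.

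Between ExSed and Ex the calls of the ribosomal, oxidative phosphorylation, red cell and erythroid lists depended on Ex 3 and, for the oxidative phosphorylation and erythroid lists, on Ex 2. With the length and GC trend removed, the ribosomal list at -0.225 (camera adjusted p = 0.00291), the oxidative phosphorylation list at -0.306 (0.00347) and the red cell list at -0.59 (0.00347) were still called. Without Sed 3, Ex 2 and Ex 3, a choice made after the data were seen that left Ex 1 alone in its group and assumed it to vary like the others, the camera direction of these 4 lists turned to higher in ExSed, with median log2 fold changes of 0.48, 0.35, 0.19 and 0.01. Without Ex 3 alone the camera adjusted p was 0.669 for ribosomal proteins, 0.132 for oxidative phosphorylation, 0.0606 for red cell genes, 0.0606 for the erythroid list and 0.0548 for the quiescence list, and the count of lists was 4. Without Ex 2 it was 0.08 for oxidative phosphorylation and 0.46 for the erythroid list. The erythroid call also ended without ExSed 1 (0.149) and without ExSed 3 (0.222). It ended with the length and GC trend removed too (0.0959), with a median that was no smaller, -0.288 (SD 1.01 over members) against -0.272 (SD 0.952). The mast cell and basophil list had 0.314 without Sed 3, Ex 2 and Ex 3. Without Ex 1 the adjusted p was 0.0576 for the immediate-early and 0.0502 for the quiescence list.

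The other 28 lists were not called between ExSed and Ex, with camera adjusted p from 0.148 to 0.94. They included S phase with a median of 0.12, G2/M with 0.13, long-term HSC with -0.17, interferon response with 0.24 and niche adhesion with 0.24. The median, mean and camera direction differed in sign for the neutrophil, heat shock, B cell, leptin and insulin, T and NK cell, glycolysis and lymphoid-primed lists. Adjusted over the list alone, Fas passed among p53 targets (0.00682), Igkc among B cell genes (0.0155) and Col1a1 among stromal genes (0.0156). Here too there was no correction across lists. Fry's mixed test called the T and NK cell list (adjusted p = 0.00622).

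The fold changes of Ex and of ExSed, both against the same Sed libraries, were compared across genes, which are not independent replicates. The Pearson correlation was 0.353, the covariance 0.339 and the share of genes with the same sign 56.6%. In simulations all 9 libraries were drawn as unchanged, with the same simulated Sed libraries in both comparisons. These gave a mean correlation of 0.501 (0.46 to 0.542 in 100 simulations), a covariance of 0.528 and a same-sign share of 66.7%. All 3 observed values lay below the simulated ones. The simulation drew each gene on its own, without the variation that genes of real libraries share, so its range is too narrow. Other splits of the real libraries gave correlations of 0.145 to 0.764. Of 100 splits, the real one included, 20 were as small, so chance is not excluded. The 3 Sed libraries were too few to split between the comparisons. The correlation was 0.688 without Sed 2 and 0.202 without Ex 1. The value for unchanged groups depends on the number of libraries per group and was not simulated for these fits.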

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

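The removal of the length and GC trend and the joint removal of Sed 3, Ex 2 and Ex 3 were chosen after the data were seen. The gene counts of 0 in the 3 comparisons and among the 3 groups stayed at 0 in edgeR under other scaling, filters, robust estimation, trend removal and each library left out (0 to 0), and in limma-voom. An FDR of 0.1 and a fit of only the 6 libraries compared, run for the 3 comparisons, also gave 0. DESeq2 gave 48 genes for Ex against Sed, 30 for ExSed against Sed, 85 for ExSed against Ex and 53 for any difference. Its spread estimate and filter differ from edgeR's, and the cause was not tested. An estimated correlation or directional fry gave 0 lists in each comparison, against 4, 6 and 7, and fry's mixed test 1, 0 and 1. Estimated correlations were 0.82 for ribosomal and 0.48 for oxidative phosphorylation genes, against the preset 0.01. With 1 library left out, the lists ran from 3 to 7 for Ex against Sed, from 5 to 10 for ExSed against Sed and from 4 to 8 for ExSed against Ex, and the correlation of fold changes from 0.202 to 0.688. Without Sed 3, Ex 2 and Ex 3 there were 8 lists for Ex against Sed. There, between ExSed and Ex, 4 lists turned direction: erythroid (adjusted p = 0.681), oxidative phosphorylation (1.23e-05), ribosomal (5.04e-13) and red cell (0.71). This fit left 1 Ex library, and Ex 1 had the steepest length slope. Over all alternatives and called lists the call was kept in 208 cases, lost in 77 and turned in these 4. Named genes stayed uncalled in 1480 cases and were called in 27, all by DESeq2. Whether depth limited calls, as for genes at 0 to 3 counts in a group, was not tested. The spread between libraries did: simulated 2-fold changes between Ex and Sed were recovered in 0 of 50 genes at the real spread and in 26 of 50 at a dispersion of 0.05.

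Replicate numbers are shared by the groups, and the labels do not say what they mark. Deviations of same-numbered libraries correlated at -0.049 to 0.199, not all above 0.1, so a pairing over all 9 libraries was not shown. With a replicate block edgeR called 0, 0, 0 and 0 genes and camera 5, 6 and 6 lists. At an unadjusted p under 0.05 edgeR gave 496, 437, 858 and 525 genes with the block, against 429, 307, 619 and 350 without it. Of the calls without it, those of the antioxidant list in ExSed against Sed (camera adjusted p = 0.123) and of the erythroid list in ExSed against Ex (0.0607) were not made. A split of the 9 libraries by replicate number gave 13 genes in the 3-group test, a hint from the data only. Of the 5 drawn splits with any gene, those with 1378, 60, 13 and 5 kept Sed 1, Ex 1 and ExSed 1 together. The split with 731 did not. A batch shared by these libraries stays open and was not tested.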

Other observations

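The tests of gene and list counts on splits of 6 libraries, of the mast cell list, of lymphoid genes, of matched lists without Sed 3, of medians over the same members and of smaller correlations were chosen after their results, or results close to them, had been seen. The count of nearly absent genes over all choices of libraries was set out beforehand, but the low Ex values of such genes had already been seen.

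Plasma cell products varied between libraries in kind as well as amount, in genes chosen after their values were seen. Igha stood at 117 and 156 CPM in Sed 2 and Sed 3 and at 1.4 CPM or less in the 7 others. Iglc1 reached 94.8 CPM in Sed 3 and 0.612 CPM at most elsewhere. Ighg2c had 181 CPM in Ex 3 and 0 counts in every other library. ExSed did not lack such products: Ighg2b had 2.72 and 3.56 CPM in ExSed 2 and ExSed 3, 10.9 CPM in Sed 3 and at most 0.0325 CPM elsewhere, and Ighg1 had 1.03 CPM in ExSed 1 and at most 0.016 CPM elsewhere. Ighm, also transcribed in early progenitors, was present throughout, from 473 CPM in ExSed 2 to 1910 CPM in Ex 3.

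The low kappa and J chain counts in ExSed were weighed against 2 explanations. A large drop in B-lymphoid-primed progenitors is argued against mainly by Dntt, which stood at 674 to 925 CPM in ExSed. Its log2 fold change between ExSed and Sed was -0.046 (SE 0.217). Dntt, Rag1, Rag2, Il7r, Vpreb1, Igll1, Ebf1 and Blnk had a median of -0.0427 (SD 0.386 over genes), with 6 of the 8 lower in ExSed. Rag1, Vpreb1, Igll1 and Ebf1 had SEs of 1.55 to 2.21, too large to exclude a drop. A few plasma cells carried over in Sed and Ex may be a source, since the depletion antibodies in the labels name CD19 and B220, low on plasma cells, and no plasma cell marker. The sort on c-Kit and Sca-1 that followed should remove cells without c-Kit, which speaks against it. The leading Igkv segment held a median of 37.9% of Igkv counts in the 5 libraries with over 10 CPM of Igkc, from 28.5% in Sed 1 to 98.4% in Sed 2, and it was a different segment in each. The median lay between the bounds set beforehand, 50% for a few cells and 20% for many, so it does not decide between few and many cells. The share does not bear on carry-over against a real difference in plasma cells, which cannot be told apart here. Of the 15 plasma cell markers, Xbp1 and Sdc1 are also progenitor genes and stood at 64.4 to 172 CPM and 27.1 to 39.6 CPM in ExSed. Of the low markers outside the immunoglobulin genes, Derl3 was higher in ExSed, at 2.31 to 5.57 CPM against 0 to 2 CPM in Sed and Ex. Prdm1 (0.877 to 4.39 CPM), Irf4 (0 to 2.8 CPM) and Mzb1 (0 to 2.47 CPM) overlapped the other groups, so these markers do not show fewer plasma cells in ExSed.

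The lower oxidative phosphorylation and ribosomal lists in ExSed were set against the length trend. The ribosomal median of -0.21 lay at the 49.9 percentile of 1000 lists of other genes matched on length, GC content and level (matched median -0.207). The trend as its source is thus not excluded. The oxidative phosphorylation median of -0.37 lay below all matched lists (percentile 0, matched 2.5 percentile -0.246). These lists were drawn gene by gene, whereas the members move together (estimated correlation 0.48), so their range is too narrow to decide. The level of the list also had a Pearson correlation of -0.985 with the length slope. Members were short and abundant (median length 710 nucleotides, median log2 CPM 7.61), and the slope was fitted over genes that include such members. That correlation is thus partly built in, and it was not computed for matched lists. Whether the trend is the whole cause of the lower list stays open. A large part of the oxidative phosphorylation median rested on Sed 3. Without that library it was -0.15, below all but 0.2% of lists matched in the same fit (2.5 percentile -0.12). The ribosomal median was then -0.000668, at the 99.9 percentile (matched median -0.0869), so without Sed 3 there was no lower ribosomal list left to explain. It lay above nearly all matched lists there, so whether the trend is its source cannot be told. After trend removal the oxidative phosphorylation median stood at -0.27 (SD 0.22 over members), against -0.13 (SD 0.127) for ribosomal genes. That left 73.6% of the oxidative phosphorylation and 64% of the ribosomal median. Other properties of the libraries that go with the slope, such as RNA quality, and the withdrawal of the wheel stay open for the oxidative phosphorylation list and were not tested.

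The higher mast cell and basophil list in Ex was set against 2 explanations. With the length and GC trend removed its median was 1.03, against 1.01, so the trend is argued against. Whether library Ex 3 alone carries it stays open. Without Ex 3 the camera adjusted p was 0.286, in a range of 0.000432 to 0.947 over all camera alternatives (fry, which tests against no change, gave 0.995), and the median was 0.0951 over the 11 members tested then, or 0.488 (SD 0.72) over the 9 tested with all libraries. The call also ended without Sed 1 (0.351), Sed 2 (0.068) or Ex 2 (0.0562), with medians over these 9 of 0.666, 1.12 and 0.981. Among single libraries left out, the median thus dropped most without Ex 3. Without Sed 3, Ex 2 and Ex 3 together, with Ex 1 alone in its group, it was -0.0989. The list level in Ex 2, 1.17, lay above the highest in Sed, 0.512 in Sed 2. That in Ex 1, -0.0642, lay below Sed 2 and Sed 3 (0.144) and above Sed 1 (-1.14). Prss34 stood above every Sed and ExSed library in all 3 Ex libraries, whereas Cpa3, an abundant mast cell protease, had 42.3 and 50.7 CPM in Ex 1 and Ex 2, 105 CPM in Ex 3 and 44 to 56.7 CPM in Sed. Basophils carried over and a change in the progenitors themselves stay open and were not tested. CD49b was among the depletion antibodies, and the sort on c-Kit and Sca-1 should remove cells without c-Kit, which speaks against carry-over of such cells. The c-Kit gate would not remove mast cells or other cells that carry c-Kit, so it does not bear on those.

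In all, 4 genes had at most 3 counts over the 3 Ex libraries and at least 0.5 CPM in each of the 6 others: Fas, Tgm5, Lpar4 and Endou. Of the 84 choices of 3 libraries, 5 gave as many, up to 8, so chance is not excluded. For ExSed there was 1 such gene, Sh3tc2 (41 of 84 choices gave as many), and for Sed 0 (84 of 84).

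The calls were counted again on other splits of the libraries. The 10 splits of 6 libraries are too few for a share under 0.05. For Ex against Sed the real split gave 4 lists and the others up to 11 (9 of 10 with as many), for ExSed against Sed 6 and up to 13 (5 of 10), and for ExSed against Ex 7 and up to 8 (4 of 10). For genes the real count was 0 in each, and the highest other was 1, 0 and 0 (10 of 10 with as many in each). The split of Ex and Sed that gave 11 lists set Sed 3, Ex 2 and Ex 3, the libraries rich in short transcripts, against the rest. Of 100 splits of the 9 libraries drawn from 280, 100 gave as many genes as the real 0. One gave 1378, with Sed 3, Ex 2 and Ex 3 as a group and Sed 1, Ex 1 and ExSed 1 as another, which points to a structure of the libraries other than the groups. The correlation of fold changes, 0.353, lay below that of simulated unchanged groups, 0.501. It was as small in 20 of the 100 splits and as large in 81, from 0.145 to 0.764 (median of the others 0.497), so chance is not excluded.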
